A study of Caenorhabditis elegans with 2 samples.

How the data were processed

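Binding of the GATA factor ELT-1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans larvae of the L2 stage, of mixed sex, from a strain that carries a transgene encoding ELT-1 fused to enhanced green fluorescent protein (eGFP). The labels give 1 group of 2 biological replicates, numbered 1 and 2, and no other group, so the samples were compared only as replicates.

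The values used are the signal of each region as the authors deposited it in 3 kinds of region list, each on the ce11 and the ce10 genome builds. Per the listing deposited with the files, the authors ranked the regions of each replicate from its own alignments with a control, ranked the regions of both replicates' pooled alignments with a control, and kept a thresholded list by the irreproducible discovery rate, which asks how well regions hold their rank between replicates. Each ranked list holds 30000 regions, most of them below any threshold. The aligner, the peak caller, the threshold and their versions are not given in the sources used here, nor is the strain from which the control was made. The thresholded list holds 351 regions on ce11, called peaks below, and all 351 were the first 351 of the pooled ranked list by signal. Read depth is unknown from these files, so intervals cover the counting of regions and not of reads.

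The score columns beside the signal were not used. Because the signal has a different scale in each list, it was compared within a list, as a rank or as a fold over the median region of that list. A peak's values in the replicates were taken from the nearest summit within 100 bp in each replicate's list, and the fold is given as the mean ± SD of both replicates. These SDs include any difference in scale between the lists. Coordinates are 1-based on ce11, the same assembly as WBcel235, and the largest region end on each chromosome lay within the reference. Gene positions came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. Coordinates were never converted between builds, and ce10 lists were used only where no annotation was needed.

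A summit lay in a promoter when it fell from 1000 bp upstream to 200 bp downstream of an annotated transcript start of a protein-coding gene, and otherwise in an exon, an intron or between genes, in that order. The background for position was the 29640 pooled regions that overlap no peak. The GATA motif WGATAR (W is A or T, R is A or G) was searched on both strands within 50 bp of the summit. Its controls were 3500 of those regions, 10 per peak, matched on GC content in bins of 5 percentage points and on promoter position, with 10 fewer than sought because some bins ran out. The same windows were searched for all 2080 distinct words of 6 bases, counting a word and its reverse complement together. Shares were compared with two-sided Fisher exact tests, with odds ratios and exact 95% intervals, and Benjamini-Hochberg adjustment over words, over chromosomes or over gene lists, at a threshold of 0.05. The regions shared by the replicates were set against 1000 random draws. Correlations are across peaks, which are not independent replicates, with intervals from 1000 bootstrap samples.

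A gene was bound when a peak summit lay in its promoter window. For each of 24 gene lists, bound members were compared with other genes among the 8131 protein-coding genes that had any ranked region in that window. The lists covered epidermal transcription factors, cuticle collagens, epidermal junctions, attachment, matrix and molting, hedgehog-related and patched-related proteins, epidermal antimicrobial peptides, GATA factors, nuclear hormone receptors, Hox genes, the heterochronic, Wnt, TGF-beta and EGF and Notch pathways, cell cycle, histones, ribosomal proteins, heat shock and proteostasis, vacuolar ATPase, and markers of intestine, body wall muscle, pharynx, all neurons, motor neurons, glia and germline. Across the lists, 6 member names were not in the annotation. Lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes elt-1 and the peaks around it, the gene whose transcript start is nearest (within 5 kb) to each of the 20 strongest peaks, the up to 4 members of each list with the strongest peaks in their promoters, and the 5 peaks whose rank differed most between replicates.

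The steps were tested on simulated data, with 20 sets of 351 regions drawn at random from the ranked regions outside peaks. Without an effect, 1 of the 20 sets passed p under 0.05 for WGATAR, 2 for promoters and 0 for chromosome X, with a mean of 0 words and 0.05 lists called. With AGATAA placed in 30% of windows, the word ranked first in 20 of 20 sets, and with 30% of the nuclear hormone receptors set as bound that list was called in 20 of 20. Alternatives changed the windows, the motif, the controls, the peaks used, the gene assignment and the build, or took the first 351 regions of a single replicate in place of the peaks. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.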

Results

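ChIP-seq regions of ELT-1-eGFP were available for 2 biological replicates of L2 larvae. ELT-1 is a GATA factor required for epidermal fate in the worm embryo. The thresholded list held 351 peaks on ce11, between 66 and 469 bp wide with a median of 264 bp. Their pooled signal ran from 24.6 to 691.8 with a median of 32.4, against a median of 7.81 over the 30000 ranked regions. The depth of the libraries is unknown, and 2 replicates limit the precision of every value below.

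The strongest peak of the genome lay in elt-1 itself (WBGene00001249, chromosome IV from 9614995 to 9620280, plus strand). It spanned 9615450 to 9615918, inside the gene and 251 bp upstream of an internal transcript start, and its summit window held 4 WGATAR sites. It ranked 1 in both replicates, at 72.0 ± 7.6-fold over the median region (SD, n = 2), and its pooled signal of 691.8 stood 3.996-fold above that of the next peak. Within 20 kb of the gene lay 9 peaks, 4 of them inside elt-1 and 5 upstream, and 4 of the 9 held WGATAR within 50 bp. The 4 next strongest of these had pooled ranks of 20, 23, 50 and 77, and 8 of the 9 had a matching summit in both replicates. The neighbouring genes aat-1, F27C8.2, mca-1 and W09C2.7 held no thresholded peak within this interval. Ranked regions of this interval that held no peak had a median signal of 10.6, against 7.81 over the pooled list.

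**Figure D1:**
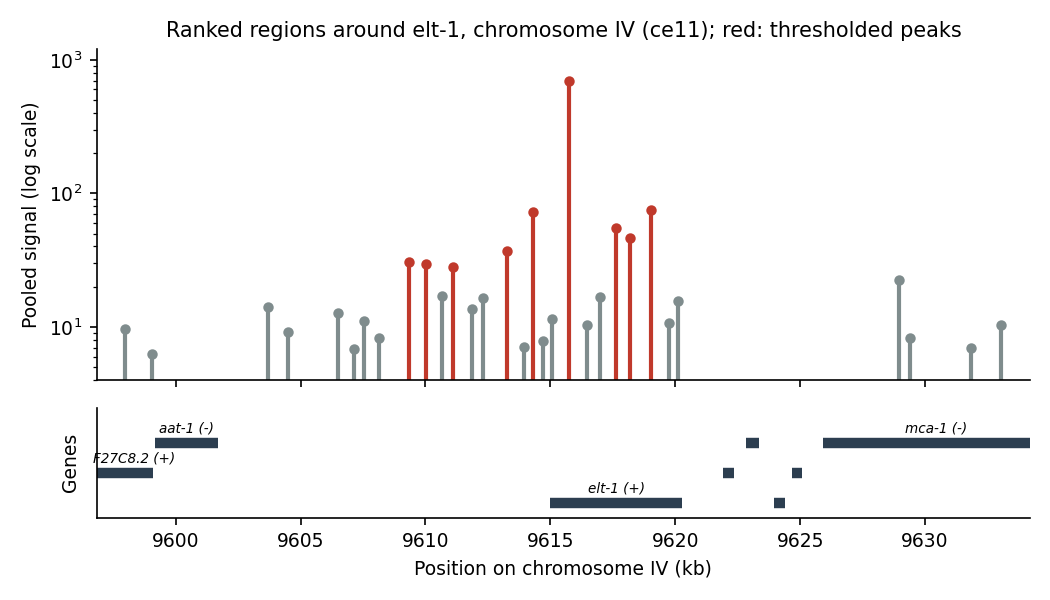
Pooled signal (log scale) of every ranked region within 20 kb of elt-1 on chromosome IV against its summit position in kb, with protein-coding genes drawn to scale below (strand in parentheses, genes over 2 kb named) and thresholded peaks in red. The 9 red peaks lie in or upstream of elt-1, and the tallest reaches 691.8.

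The second peak in rank (chromosome V from 14506824 to 14507016) lay between genes, 1325 bp upstream of R02D5.1, at 18.4 ± 3.9-fold over the median region (SD, n = 2). A peak in an intron of fasn-1, which encodes fatty acid synthase (chromosome I from 8985987 to 8986169), reached 14.5 ± 0.97-fold. An intronic peak with egl-18 as its nearest gene, a GATA factor of the seam cells (chromosome IV from 1911405 to 1911535), reached 12.57 ± 4.3-fold. The 4th peak lay in an exon near srw-85 at 13.7 ± 6.6-fold, the 5th in an intron near spsb-1 at 12.63 ± 1.1-fold, and the 6th 3982 bp upstream of the nuclear hormone receptor gene nhr-17 at 11 ± 1.9-fold. The remaining nearest genes were sdz-19, F53E4.1, the cytochrome P450 gene cyp-14A5, scd-1 with 2 peaks, T23E7.6, W04D12.1, hir-1, mdl-1, dmd-7, nhr-155, hsp-3 and elt-1 again. Their peaks lay at 7.65 to 10.6-fold. Of these 20 peaks, 7 lay on X, 7 on V, 6 in promoters, and 13 held WGATAR within 50 bp. Among the first 20 regions of each replicate were 16 of them in replicate 1 and 17 in replicate 2.

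The replicates shared their strongest regions far more often than chance. Of the first 351 regions of replicate 1, 169 (48.1%) had a summit within 100 bp of a summit among the first 351 of replicate 2, against a mean of 0.975% and a highest value of 3.13% in 1000 random draws (permutation p = 0.001, the smallest they can give). Of the 351 peaks, 273 (77.8%) stood among the first 351 regions of replicate 1 and 221 (63.0%) among those of replicate 2, and 26 stood in neither. The median peak lay 4.30-fold over the median region in replicate 1 and 2.84-fold in replicate 2, and 273 of the 332 peaks matched in both had the higher fold in replicate 1.

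Signals of the 332 matched peaks correlated weakly between the replicates, with a Spearman rho of 0.326 (95% interval 0.216 to 0.424) and a Pearson r of 0.498 on log2 signal, across peaks. Without the strongest peak r was 0.435. Of the matched peaks, the 5 that differed most in rank were all stronger in replicate 1. They lay nearest to gldi-3 (rank 287 in replicate 1 and 26651 in replicate 2), the cytochrome P450 gene cyp-13A2 (150 and 15567), Y67D8C.9 (64 and 12759, over 10 kb away), dab-1 (255 and 11833) and W02H3.3 (93 and 10541). The peaks were selected on pooled signal, and over the lower 175 of them, 160 matched, rho was -0.459. Those 175 lie between pooled signals of 24.6 and 32.4, and the pooled signal draws on both replicates. Within so narrow a band, a higher value in 1 replicate tends to go with a lower value in the other. This rho is therefore no measure of how well the replicates agree, and the same selection may lower rho over all matched peaks.

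**Figure D2:**
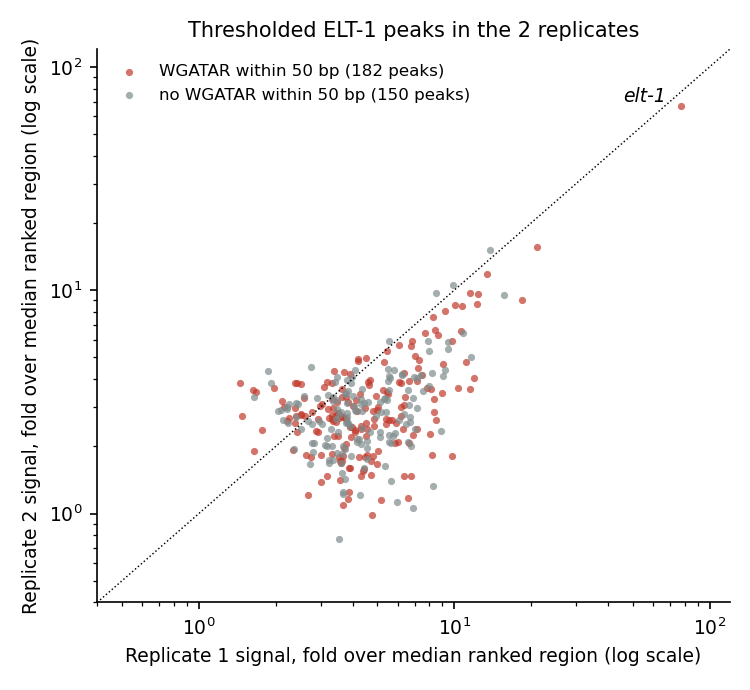
Signal of the 332 matched peaks in replicate 1 (horizontal) and replicate 2 (vertical), each as fold over the median ranked region of its own list, both axes on a log scale, with the diagonal dotted and peaks holding WGATAR in red. The elt-1 peak stands apart at 77.4 and 66.6-fold, and most other points lie below the diagonal.

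GATA sites marked the peak summits. WGATAR lay within 50 bp of the summit in 189 of 351 peaks (53.8%) and in 650 of 3500 matched controls (18.6%), an odds ratio of 5.11 (4.05 to 6.46, two-sided Fisher exact p = 6.6e-44). The odds ratio was lower with other choices: 3.28 with replicate 2 alone and 3.48 against flanks of the same peaks. Against peak windows shuffled with their counts of neighbouring bases kept, it was 3.37. Sites were densest at the summit, with 8.83 per kb within 25 bp against 2.21 in controls. Their density was 2.79 against 2.76 at 75 to 100 bp, 3.48 against 2.54 at 100 to 150 bp and 3.05 against 2.45 at 150 to 200 bp. The form AGATAA occurred in 33.6% of peaks and 6.26% of controls (odds ratio 7.58, 5.79 to 9.91), and TGATAA in 13.1% and 6.86% (odds ratio 2.05, 1.43 to 2.89). By place, WGATAR was held by 48.3% of the 145 promoter peaks, 64.7% of the 17 exon peaks, 58.3% of the 72 intron peaks and 56.4% of the 117 intergenic peaks.

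The search of all words gave the same core first. Of 2080 words, 139 were more frequent in peaks and 94 less frequent at an adjusted p under 0.05 (Fisher exact tests). The leading words were AGATAA, GATAAG in 24.2% of peaks against 4.83% of controls (adjusted Fisher exact p = 6.1e-27), and AAAGAT in 31.3% against 8.54% (adjusted p = 7.8e-27). Of the 139 words, 22 contained the whole of GATA on either strand and 117 did not. Words in the same window can overlap, so these are not counts of independent words. Some of the 117, such as AAAGAT and ATAAGA, can share bases with AGATAA or GATAAG at the same site. How many of the 117 overlapped a GATA site was not tested, so they are not shown to be separate from it. Among the words less frequent in peaks was CTGAAA, in 4.27% against 14.1% (adjusted exact p = 5.3e-07). Controls were matched on promoter position but not on exons, which held 4.84% of peaks and 25.7% of other ranked regions. A word difference is therefore not separated from a difference in place. With the first 351 regions of replicate 2 alone, 88 words were more frequent, again led by AGATAA.

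**Figure D3:**
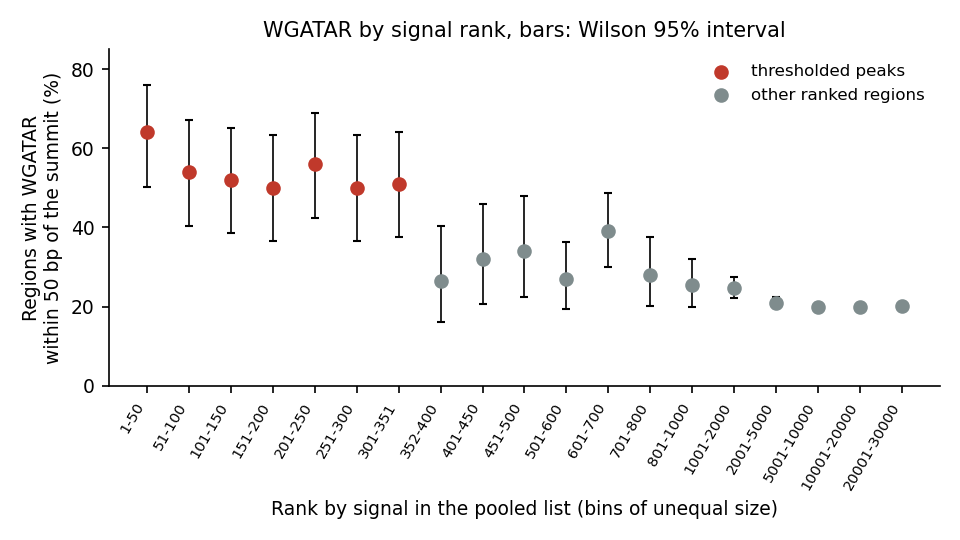
Percent of pooled ranked regions with WGATAR within 50 bp of the summit (vertical) in bins of signal rank (horizontal, bins of unequal size), with Wilson 95% intervals, peaks in red and other regions in grey. Bins of peaks lie between 50 and 64%, and the first bin below the threshold is at 26.5%.

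Peaks lay more often in promoters and between genes, and less often in exons, than other ranked regions. Promoters held 145 peaks (41.3%) against 29.9% of the 29640 other regions (odds ratio 1.65, 1.32 to 2.05; adjusted Fisher exact p = 1.0e-05), and intergenic positions 117 (33.3%) against 21.6% (odds ratio 1.81; adjusted p = 1.2e-06). Exons held 17 peaks (4.84%) against 25.7% (odds ratio 0.147; adjusted exact p = 2.7e-24), and with replicate 2 alone the share was 9.97% (odds ratio 0.334). Introns held 72 (20.5%) against 22.7%, which did not pass the exact test (p = 0.37). The shares depend on each other, so that a lower exon share raises the rest. The median distance to the nearest transcript start was 1220 bp for peaks and 1166 bp for other ranked regions, so peaks lay no closer by this measure. From the nearest transcript start, 32 peaks (9.12%) lay beyond 5 kb.

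Chromosome X carried 97 peaks (27.6%), above its 19.8% of the other ranked regions and its 17.7% of the nuclear genome (odds ratio 1.54, 1.21 to 1.963; adjusted Fisher exact p = 0.0027). Peaks on X included those in the promoters of hsp-3, nhr-32, dpy-7, lpr-3, sma-9, dlg-1, del-1 and sym-1. None of the 5 autosomes passed the test after adjustment. Chromosome III had the lowest share relative to other regions, 9.97% against 14.1% (exact p = 0.025, adjusted p = 0.075).

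Peaks lay in the promoters of 161 of the 8131 genes tested (1.98%), and 5 of the 24 gene lists had more bound members than other genes, all at an adjusted Fisher exact p under 0.05. Nuclear hormone receptor genes led, with 19 of 140 bound (13.6%) against 1.78% of other genes (odds ratio 8.67, 4.91 to 14.6; adjusted Fisher exact p = 6.3e-10). These 19 genes held 17 distinct peaks, 5 of them with WGATAR within 50 bp, and 9 of the genes lay on V. The strongest were at nhr-155 (chromosome V, summit 212 bp upstream, 8.32 ± 4.7-fold over the median region, SD, n = 2), nhr-32 (X, 6.82 ± 3.4-fold), nhr-168 (V, 6.90 ± 1.4-fold) and nhr-175 (V, 5.87 ± 3.2-fold).

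Of genes for epidermal junctions, attachment, apical matrix and molting, 5 of 32 were bound (odds ratio 9.42, 2.80 to 25.27; adjusted exact p = 0.0045), among them the matrix gene noah-1 (5.02 ± 4.5-fold, SD, n = 2), the lipocalin-related gene lpr-3 (4.01 ± 0.43-fold), the junction gene dlg-1 (2.57 ± 0.23-fold) and sym-1 (2.56 ± 0.22-fold). Of hedgehog-related and patched-related genes, 5 of 40 were bound (odds ratio 7.26, 2.19 to 18.96; adjusted exact p = 0.0086). They included grd-3 (5.10 ± 1.0-fold), grd-10 (4.47 ± 1.4-fold) and grd-13 (4.34 ± 2.7-fold), 3 neighbours on chromosome IV with separate peaks, and the patched-related gene ptr-18 (4.50 ± 0.42-fold). The 3 neighbours lie from 3438312 to 3441841, and the exact test counts them as independent genes, so its p-value does not allow for their shared locus. The 5th members, named after their values were seen, were ifb-1, an intermediate filament gene, and wrt-10. With replicate 2 alone 3 lists passed in place of 5, and neither the junction list (3 of 26, odds ratio 6.38, adjusted exact p = 0.073) nor the hedgehog list (4 of 40, odds ratio 5.46, adjusted p = 0.051) was among them. Without the weaker 175 peaks the junction list did not pass either (2 of 32, odds ratio 7.75, adjusted exact p = 0.15). The hedgehog list passed there (5 of 40, odds ratio 17.3, adjusted exact p = 0.00055).

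Heat shock and proteostasis genes and ribosomal protein genes were the other called lists. Of the former, 3 of 12 were bound (odds ratio 16.8, 2.89 to 68.0; adjusted exact p = 0.0088), namely the endoplasmic reticulum chaperone genes hsp-3 (7.93 ± 0.43-fold, SD, n = 2) and enpl-1 (5.83 ± 2.4-fold) and the chaperonin gene cct-1 (2.45 ± 1.7-fold), whose peak also lay in the promoter of mig-5, a Dishevelled gene of the Wnt list. Of ribosomal protein genes, 5 of 60 were bound (odds ratio 4.61, 1.42 to 11.7; adjusted exact p = 0.031), with rpl-3 at 5.53 ± 2.0-fold, rpl-35 at 4.01 ± 1.6-fold, rpl-20 at 3.16 ± 1.4-fold and rpl-15 at 3.16 ± 0.87-fold. The 5th, rpl-12, was named after its value was seen, and 0 of the 5 peaks held WGATAR within 50 bp. Assigning each peak to its nearest gene ended the call of the heat shock list (2 of 20, odds ratio 5.43, adjusted exact p = 0.18). With the upper 176 peaks the ribosomal list was not called (3 of 60, adjusted exact p = 0.092), at a higher odds ratio of 6.19 from fewer bound genes.

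Among the 19 lists that did not pass, epidermal transcription factors had 2 of 10 members bound, elt-1 and the molting regulator nhr-23 (2.495 ± 1.5-fold, SD, n = 2), at an adjusted exact p of 0.063. This list passed with a window from 2000 bp upstream to 500 bp downstream (3 of 10, adjusted exact p = 0.0036), by nearest transcript start (4 of 11, adjusted p = 0.00038) and against all annotated genes (2 of 15, adjusted p = 0.025). It also passed with peaks holding WGATAR within 100 bp alone (2 of 10, adjusted exact p = 0.034) and with replicate 1 alone (2 of 8, adjusted p = 0.040). It did not pass with replicate 2 alone (1 of 11, adjusted exact p = 0.48), with a window from 500 bp upstream to 100 bp downstream (1 of 10, adjusted p = 0.43) or with the upper 176 peaks (1 of 10, adjusted p = 0.29). Without the peaks within 20 kb of elt-1, an alternative chosen after the data were seen, it had 1 of 10 bound (odds ratio 5.56, adjusted exact p = 0.42). The GATA factors had only elt-1 bound of 5 (adjusted exact p = 0.29), and passed with the wider window (3 of 5, adjusted p = 0.00053) and by nearest transcript start (3 of 8, adjusted p = 0.0020); without the peaks around elt-1, 0 of 5 were bound. Cuticle collagens had 3 of 73 bound (adjusted exact p = 0.38), dpy-7 at 4.13 ± 3.8-fold, dpy-10 at 3.26 ± 1.8-fold and col-172 at 3.07 ± 1.2-fold, and passed with replicate 1 alone (6 of 79, odds ratio 4.14, adjusted exact p = 0.024) but not with replicate 2 alone (1 of 79, odds ratio 0.615, adjusted exact p = 1). In 7 further lists peaks lay at nlp-24 of the antimicrobial peptides (matched in replicate 2 only), lin-42 of the heterochronic pathway (3.55 ± 0.31-fold), sma-9 of the TGF-beta pathway (3.21 ± 1.3-fold), fzr-1 of the cell cycle list (4.35 ± 1.6-fold), del-1 of the motor neuron list (2.59 ± 1.4-fold), mig-5 of the Wnt pathway, and between the histone genes his-67 and his-68 (2.93 ± 0.51-fold). None of the members tested were bound in the lists of intestine (0 of 12), body wall muscle (0 of 15), pharynx (0 of 6), all neurons (0 of 19), glia (0 of 5), germline (0 of 15), Hox genes (0 of 5), the vacuolar ATPase (0 of 13) and EGF, Notch and vulval induction (0 of 20), and their small sizes leave upper bounds of the odds ratio from 10.1 to 54.4.

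**Figure D4:**
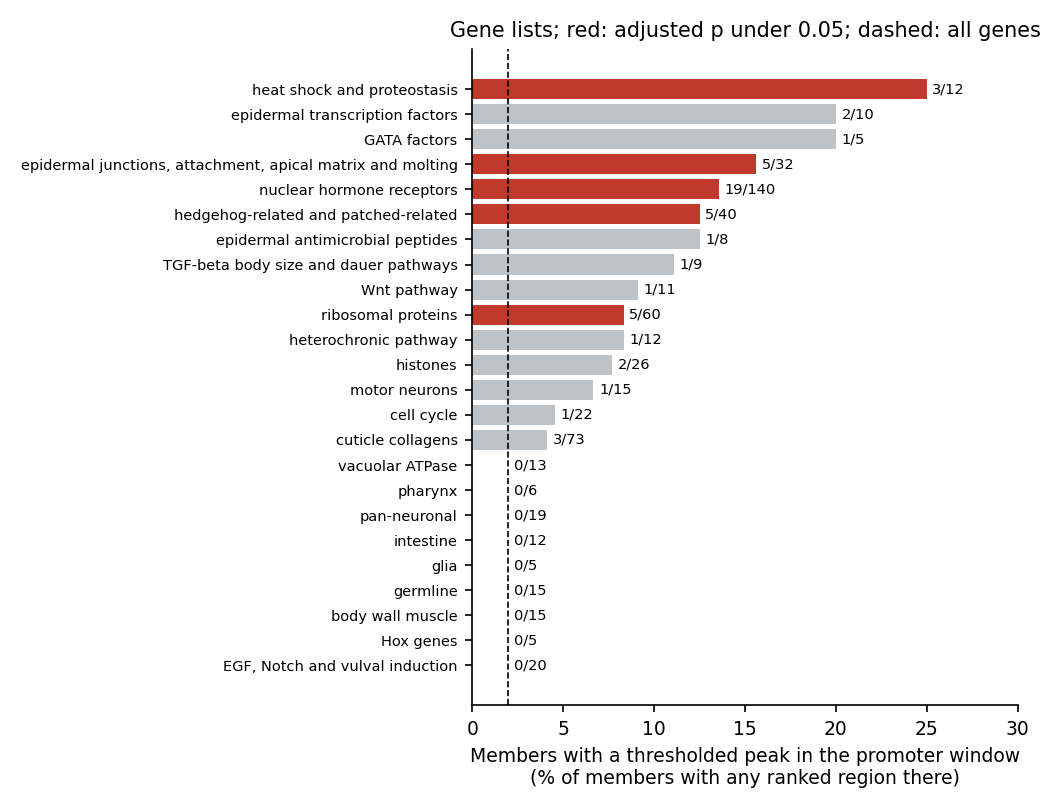
Percent of each list's members with any ranked region in the promoter window that held a thresholded peak there (horizontal bars, counts beside them), with lists of adjusted p under 0.05 in red and the 1.98% over all genes as a dashed line. Heat shock genes (3 of 12) have the longest bar, and nuclear hormone receptors (19 of 140) the most bound members.

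Genes for tRNA, snRNA and snoRNA, which are highly transcribed, lay within 200 bp of 7 peak summits (1.99%) and of 0.995% of other ranked regions. The difference did not pass the test (odds ratio 2.02, 0.80 to 4.27; two-sided Fisher exact p = 0.094). It passed within 500 bp (3.13% against 1.57%, exact p = 0.029) and with replicate 2 alone (2.56% against 0.986%, p = 0.0095).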

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

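The tests of the whole cause of the strongest peak and of peaks without WGATAR were chosen after the results were seen, and so was the comparison of regions below the threshold. Regions outside the thresholded list still held GATA sites: of the 649 regions from rank 352 to rank 1000 that overlap no peak, 29.4% had WGATAR within 50 bp, against 4999 of the 24995 regions below rank 5000 (odds ratio 1.67, 1.397 to 1.985; two-sided Fisher exact p = 1.9e-08). These regions are part of the background in the comparisons of peaks, and no explanation was tested for their signal.

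The strain carries an elt-1 transgene, so extra copies could raise the locus. Ranked regions within 20 kb of elt-1 that hold no peak had a median signal at the 99.7th percentile of windows of the same size (lower bootstrap bound 89.4). The percentile was 99.97 (lower bound 86.4) in replicate 1 and 97.6 (lower bound 47.1) in replicate 2. As these bounds lie below the preset value of 95, and weak binding near elt-1 would raise these regions too, extra copies and binding cannot be told apart here. Division by the excess of these regions (1.36-fold) left the strongest peak 2.94-fold over the next, and 2.46-fold and 3.42-fold in replicates 1 and 2, but regions without a peak are chosen for low signal, so that the ratio could not fall under 1.26 in the pooled list or 1.17 in replicate 2, and could in replicate 1 alone (0.664). With the other peaks of the locus included, the ratio within 20 kb was 2.36 (bootstrap interval 1.83 to 3.04) in the pooled list. It was 2.15 (1.54 to 2.48) in replicate 1 and 2.71 (2.06 to 4.06) in replicate 2. For the gene alone the pooled ratio was 1.93 (0.569 to 2.88). These ratios cannot count against copies. Each list is cut at a lowest signal, in the pooled list 5.90 against a median of 7.81. Regions lifted over the cut by copies would join the list and lower the locus median, so the excess may understate copies. Whether signal rises in proportion to copies is also unknown. Copies of either span therefore stay open as the whole cause of the strongest peak's lead over the next peak. The ranked regions beside the strongest peak in the gene had pooled signals of 11.4 (summit 9615072) and 10.3 (summit 9616460), against 691.8. Copies of either span would lift these regions too. This contrast thus argues against copies as the whole cause of the peak's height over its surroundings. The spans were separated after a joint test of both had not passed. No biological explanation was tested, since the design has 1 group.

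For the excess of peaks on X, denser GATA words along the whole chromosome were argued against as the cause. WGATAR was 1.10 times as dense on X as on the autosomes (2.57 against 2.33 per kb), under the preset bound of 1.2. The density within ranked regions was not compared between X and the autosomes, so denser sites in those regions stay open. Of the peaks holding WGATAR, a subset chosen after the data were seen, 32.3% lay on X, against 27.6% of all peaks. Peaks without WGATAR were not tested separately for their share on X. A generally higher signal on X stays open: 23.3% of the regions from rank 352 to 1000 lay on X, and their difference from the 27.6% of peaks did not pass the test (Fisher exact p = 0.14). No biological explanation was tested.

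Of the 351 peaks, 162 lacked WGATAR within 50 bp. Other words with a GATA core are a candidate explanation for part of them: 62.3% of these peaks held GATA against 34.8% of controls without WGATAR, an excess of 27.5 percentage points (20.5 to 35.2), and CGATAA led their words (20.99% against 4.32%, adjusted exact p = 6.5e-10). Both values come from the same windows and restate each other in part, and the GATA share was not tested in other regions. A site between 51 and 200 bp away was 4.22 percentage points more frequent than in controls (-4.10 to 12.65), and the promoter share was 46.3% against 37.04% in peaks with WGATAR (Fisher exact p = 0.083), so that both of these explanations stay open. No biological explanation was tested.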

How the results depend on the processing

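The split of the correlation by signal or without its strongest peak, X among peaks with WGATAR alone, and lists without the peaks around elt-1 were chosen after the data were seen. The WGATAR excess kept its direction and its side of the threshold under all 12 alternatives, with odds ratios from 2.05 for TGATAA to 7.58 for AGATAA, and from 3.28 to 4.64 with a single replicate. So did promoters under 6 (1.36 to 1.68), chromosome X under 7 (1.43 to 1.93), nuclear hormone receptors under 9 (5.88 to 10.3) and the shared regions under 6 (34.2 to 49.6%). The number of peaks was 360 on ce10 and 176 in the upper part by signal, which has that size by construction. The correlation was 0.341 over the upper part and turned to -0.459 over the lower part. Selection on pooled signal favours a negative value within the narrow band of the lower part, and may lower the value over all peaks. How far it lowers either was not tested. Against flanks of the same peaks, 214 words were more frequent, led by GATAAG, and with a single replicate 88 to 126. Lists called numbered 3 with the upper 176 peaks, fewer peaks giving fewer bound genes, and 3 to 7 with a single replicate. With peaks holding WGATAR within 100 bp alone, the ribosomal odds ratio was 0, with 0 of 60 members bound, as those peaks lack the motif there. Small RNA genes passed within 500 bp (odds ratio 2.03) and gave 1.60 to 2.64 with a single replicate. The cause was not tested for the words, for small RNA genes or for the differences between replicates. Leaving out a replicate gives no value for the number of peaks, the shared regions or the correlation, which need both. No paired analysis of samples was possible because there is 1 group. Flanks and shuffled windows come from the same peaks, but the Fisher tests against them did not use that pairing. Depth is unknown, so its effect on the lower signal folds of replicate 2 could not be measured.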

Other observations

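The tests below were chosen after the values were seen. Among windows with exactly 1 of the words AGATAA and TGATAA, 106 of 140 peaks (75.7%) and 207 of 435 controls (47.6%) held AGATAA, an odds ratio of 3.43 (2.198 to 5.44), which restates the shares that prompted it. In other regions, from rank 352 to 1000, 92 of 131 such windows (70.2%) held AGATAA, against 287 of 696 (41.2%) in matched controls below rank 5000, an odds ratio of 3.36 (2.21 to 5.17; two-sided Fisher exact p = 9.9e-10). A hypothesis is that regions of higher ELT-1 signal may favour AGATAA over TGATAA.

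The share of regions with WGATAR was 50.98% in the last 51 peaks, down to rank 351, and 26.5% in the 49 regions of rank 352 to 400 (Fisher exact p = 0.015). In a logistic model on log2 signal over the first 1000 regions, lying above the threshold had an odds ratio of 2.04 (1.32 to 3.16). Both values use the regions in which the drop was seen and so restate it, and the drop was not tested in other regions.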
